A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

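Transcript levels of budding yeast were compared on 2-colour Agilent expression arrays between a strain lacking ZTA1 (YBR046C, called ∆zta1) and its wild type, FY834α. Per the labels, the cells grew exponentially in rich YPD medium, and RNA came from 3 pairs of untreated cultures and from 3 pairs treated with 10 mM hydrogen peroxide (H2O2) for 30 min. Each pair was hybridised on 2 arrays with the dyes swapped, which makes 12 arrays for 6 pairs of cultures. In either treatment the description of the first array of replicate 3 says replicate 2 instead, and arrays were paired by their titles. No array set a treated sample against an untreated one, so the response of either strain to peroxide was not measured.

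The deposited table holds 1 log2 ratio per probe and array, and the authors' background correction, normalisation, scale and direction are not stated in the labels. limma is the only program named in the submitters' processing notes, with no version. The values were read as log2 because limma writes log ratios in that base, and because the most negative value, -6.34, would stand for an implausibly large ratio in base 10. Every column was read as ∆zta1 over wild type, dye swaps included, from the sample titles and from ZTA1 itself, which was strongly negative on all 12 arrays. The medians of the columns lay between -0.0172 and 0.0165, so the values were already close to centred. The table has no intensities, spot flags or slide numbers, and none of its cells is missing. Signal over background is therefore unknown, and the number of arrays limits the precision.

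Of the 6256 probes, 5620 had 1 gene in the platform annotation, none had several, and 636 had none and stayed unnamed. All 5620 gene identifiers were found in a RefSeq gene table of assembly R64, which was used only for names and for the order of genes along chromosomes. Probes of the same gene were averaged, which concerned 25 genes and left 5594 genes to test. A RefSeq accession was shared by probes of different genes in 21 cases, so near-identical family members may share signal.

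The 2 arrays of a pair were averaged into 1 replicate, in which a dye effect cancels. limma 3.58.1 (lmFit and eBayes, R 4.3.3) was fitted to the 6 pair means with 1 mean per treatment and a shared spread, leaving 4 residual degrees of freedom. There were 4 two-sided comparisons, namely ∆zta1 against wild type in untreated cells, the same under H2O2, the difference between these strain ratios, and their mean. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Values are given with the SD over pairs or with limma's standard error.

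The text names ZTA1, up to 10 genes per direction that passed with the same sign in every pair and in either dye orientation, and up to 4 members of each gene list it describes. It also names the arginine biosynthesis genes and the neighbours of ZTA1. Where a comparison had fewer than 5 such genes, the 5 genes per direction with the smallest p are named as not passing.

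There were 32 gene lists with 912 measured members, drawn up from textbook knowledge. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison. With an estimated correlation camera also rests on the few residual degrees of freedom, so few lists could pass whatever their correlation. For the genes around ZTA1 in untreated cells the estimate was -0.037, below the preset value. Even so, the unadjusted camera p rose from 0.0020 to 0.034. How many shifted lists that test finds was not simulated. The lists, the tests, the rule for naming genes and all but 1 of the alternative settings were fixed before the data were examined. The added setting weighted the pairs by quality.

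The fits were tested on simulated data with the measured genes and spread, in 20 runs with 50 genes changed at each size. In untreated cells 82.6% of genes changed by a log2 ratio of 0.25 and 98.0% of those changed by 0.5 were found. Under H2O2 the shares were 83.5% and 98.2%. For the difference between treatments they were 58.6% and 93.6%, and for the mean of both treatments 95.0% and 99.0%. False calls made up 4.4% to 5.3% of the calls. Each run held changed genes of several sizes at once, many more than passed in the measured data. That eases the Benjamini-Hochberg threshold, so fewer would be found where few genes change. The values of each gene were drawn from a normal spread, with no pair set apart from the others. For the mean of both treatments, camera at the preset correlation found a list of 30 genes shifted by 0.1 in 20 of 20 runs. The simulated genes were independent, while those of real lists such as arginine biosynthesis move together. These runs therefore do not test the calls of such lists.

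Alternatives were each array centred on its median, or centred and scaled, each dye orientation alone, and all 12 arrays in 1 fit with a dye term and the pair as a random block. Others were a fit of each treatment alone, the replicate number as a block, robust eBayes, and each pair left out in turn. A test per probe, an adjusted p under 0.01, a minimum of 1.5-fold, and lists without shared members were also tried. Another background correction, a filter on dim probes and a slide block were planned and not run, because the table holds nothing to base them on.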

Results

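The series measured how the loss of ZTA1 alters transcript levels in yeast with and without oxidative stress. ZTA1 encodes zeta-crystallin, a quinone oxidoreductase that the series' title describes as a protein binding AU-rich elements of messenger RNA. Ratios of ∆zta1 to wild type were available for 5594 genes in 3 pairs of untreated cultures and 3 pairs treated with 10 mM H2O2 for 30 min.

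ZTA1 was low in every ∆zta1 sample. Its log2 ratio was -5.84, -4.32 and -5.73 in the untreated pairs and -4.96, -4.56 and -4.58 in the H2O2 pairs. On single arrays it ranged from -3.21 to -6.34, so no array went against the strains named in its label. Markers of cell type did not pass over both treatments with all 6 pairs. The medians were -0.022 for 7 a-cell genes (camera adjusted p = 0.339) and 0.0028 for 6 alpha-cell genes, whose mean and test pointed downward (mean -0.013, adjusted p = 0.678). Without untreated replicate 2 the alpha-cell genes passed as lower (median -0.070, adjusted p = 0.0223, or 0.780 with an estimated correlation).

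The ratios carried a dye effect of a size similar to the strain ratios. Across genes, the dye part of a pair had an SD of 0.103 to 0.135, and the ratio of a pair an SD of 0.111 to 0.161. Across genes, which are not independent replicates, arrays of the same dye orientation had a median Pearson correlation of 0.690, while the 2 arrays of a pair had a median of -0.0093 once both were expressed as ∆zta1 over wild type. Averaging a pair cancels that effect. Between 4 and 5 genes differed by more than 2-fold in 5 of the pairs, and 20 did so in untreated replicate 2, which stood apart from the others.

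In untreated cells, the first comparison asked which transcripts differ without ZTA1 in the absence of peroxide. Apart from ZTA1 itself, the genes that passed were those directly beside it and a small set of others. FMP23 (YBR047W), which encodes a mitochondrial protein and lies next to ZTA1, was 5.16-fold higher in ∆zta1, a log2 ratio of 2.37 ± 0.82 (SD, n = 3 pairs, limma adjusted p = 0.0030). GIP1 (YBR045C), the neighbour on the other side and a meiotic regulator of protein phosphatase, was 1.96-fold higher (0.97 ± 0.13, adjusted p = 4.9e-05). NOB1 (YOR056C), an endonuclease of ribosomal RNA maturation, rose by 0.69 ± 0.093 (adjusted p = 6.0e-05). IMD2 (YHR216W), an IMP dehydrogenase of guanine nucleotide synthesis, rose by 0.40 ± 0.13 (adjusted p = 0.0079).

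Apart from ZTA1, 6 genes fell in untreated ∆zta1 cells. YCL021W-A, an uncharacterised gene, was 16.6-fold lower, with a log2 ratio of -4.06 ± 0.92 (SD, n = 3 pairs, limma adjusted p = 0.00030). COS12 (YGL263W), of a family of membrane proteins encoded near telomeres, was 2.61-fold lower (-1.38 ± 0.24, adjusted p = 8.6e-05). YIR042C (-0.73), YGL262W (-0.55), YGL258W-A (-0.33) and BOP2 (YLR267W, -0.25, adjusted p = 0.031) fell as well. In all, 4 genes rose and 7 fell among 5594, ZTA1 included, each with the same direction in all 3 pairs. Of these 11, 9 also passed when any 1 of the 6 pairs was left out. BOP2 passed in none of these 6 fits (largest adjusted p = 0.196), and IMD2 did not pass without untreated replicate 3 (adjusted p = 0.131).

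**Figure D1:**
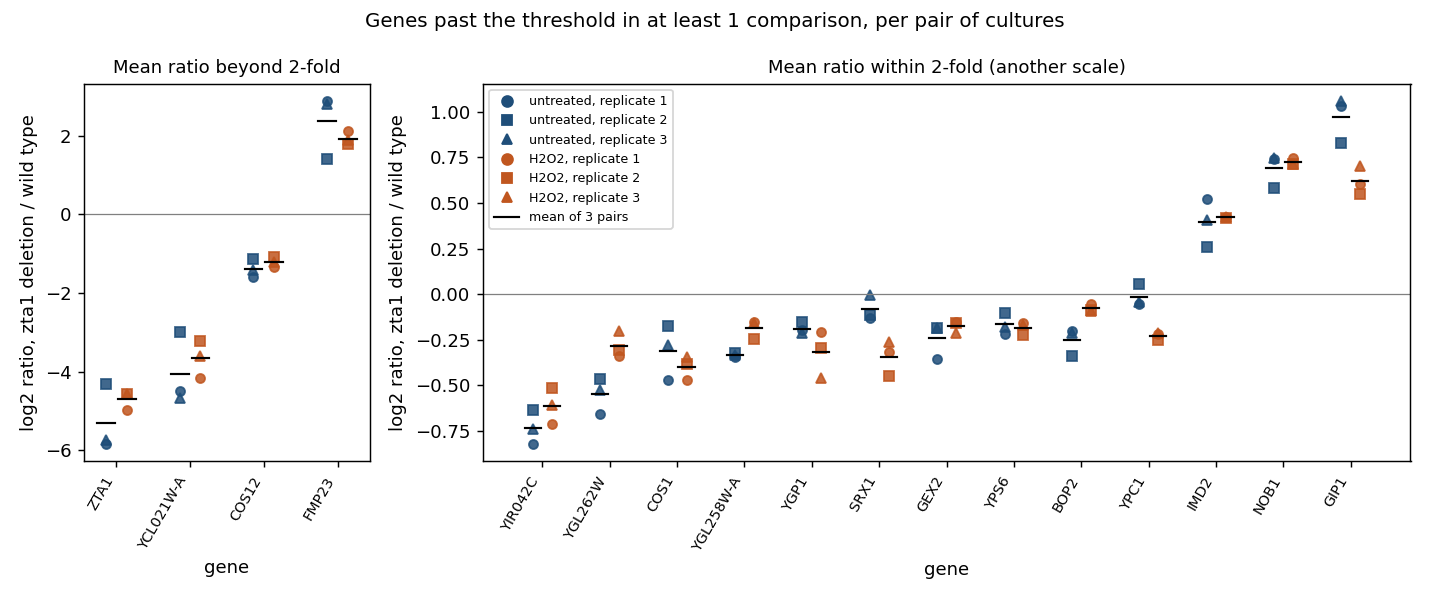
Log2 ratio of ∆zta1 over wild type (vertical axis) in each of the 6 pairs for every gene past the threshold in at least 1 comparison (horizontal axis), with untreated and H2O2 pairs in separate colours, bars for the mean of 3 pairs, and another vertical scale for the genes within 2-fold. ZTA1, YCL021W-A, COS12 and FMP23 lie beyond 2-fold, with mean ratios over both treatments of -5.00, -3.86, -1.30 and 2.15.

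Genes of amino acid synthesis had lower ratios as groups in untreated cells, and this rested on untreated replicate 2. All 8 measured arginine biosynthesis genes had ratios below 0, with a median of -0.43 (camera adjusted p = 3.8e-07, and adjusted p = 0.448 with an estimated correlation), yet none passed over all genes or adjusted over the list alone. ARG1, argininosuccinate synthase, had log2 ratios of 0.31, -1.90 and -0.41 in the 3 pairs, and ARG4, argininosuccinate lyase, had -0.0073, -1.25 and -0.33. ARG3 and ARG7 had mean ratios of -0.52 and -0.49, and ORT1, CPA1, ARG2 and ARG8 lay closer to 0. The median of the list was 0.041, -1.14 and -0.15 in the 3 untreated pairs, and -0.048 without untreated replicate 2 (adjusted p = 0.0590). It was -0.67 without untreated replicate 1 (adjusted p = 2.1e-10, or 0.616 with an estimated correlation).

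The 9 lysine biosynthesis genes were all below 0 (median -0.086, adjusted p = 4.3e-06), as were all but 5 of 47 other amino acid biosynthesis genes (median -0.13, adjusted p = 5.3e-15). LYS1 (-0.35), LYS20 (-0.34), HOM3 (-0.33), ARO3 (-0.32) and HIS4 (-0.31) had the lowest mean ratios named from these lists, and none of the members passed over all genes or adjusted over the list alone. Genes under nitrogen catabolite repression had a median of -0.052 (adjusted p = 6.1e-06) and 3 of 29 were above 0, none passing over all genes or adjusted over the list alone. With an estimated correlation the adjusted p was 0.448 for each of these lists. Without untreated replicate 2 the medians were -0.017 for lysine (adjusted p = 0.226), -0.019 for the other amino acids (adjusted p = 0.0349, or 0.828 with an estimated correlation) and -0.015 for nitrogen catabolite genes (adjusted p = 0.188). The calls held with larger medians of -0.15 for lysine and -0.21 for the other amino acids without untreated replicate 1, and of -0.13 for lysine and -0.078 for nitrogen catabolite genes without untreated replicate 3. With an estimated correlation the adjusted p in these fits was 0.616 and 0.656.

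**Figure D2:**
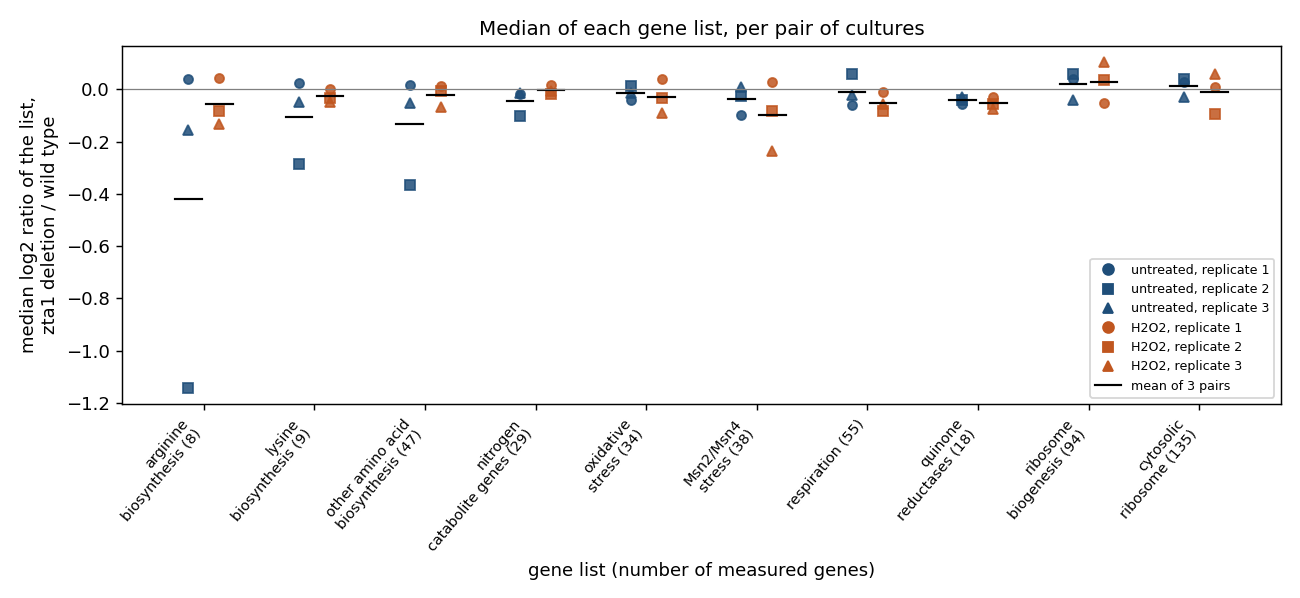
Median log2 ratio of ∆zta1 over wild type (vertical axis) of 10 gene lists (horizontal axis, with the number of measured genes) in each of the 6 pairs, with bars for the mean of the 3 medians per treatment. The arginine list stood at -1.14 in untreated replicate 2 and between -0.15 and 0.043 in the other pairs.

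The remaining list calls in untreated cells were small shifts. Iron uptake genes (19 genes, median -0.055, adjusted p = 2.9e-07), phosphate-regulated genes (18 genes, median -0.053, adjusted p = 9.9e-05) and quinone or related reductases (18 genes, median -0.030, adjusted p = 0.0289) were lower, each with adjusted p = 0.448 with an estimated correlation. The lowest iron gene was SIT1 (-0.22), and TIS11 (-0.18) was the only member of these 3 lists to pass when adjusted over the list alone. Without untreated replicate 2 the median of the iron genes was -0.023 (adjusted p = 0.0453, or 0.828 with an estimated correlation). Stress genes under Msn2 and Msn4 (38 genes, median -0.037, adjusted p = 0.0010) were lower, with HSP12 at -0.34 the only member to pass adjusted over the list alone, while ribosome biogenesis genes (94 genes, median 0.025, adjusted p = 4.6e-06) and cytosolic ribosomal protein genes (135 genes, median 0.015, adjusted p = 0.0147) were higher. With an estimated correlation these had adjusted p = 0.875, 0.883 and 0.974. Sulfur and methionine genes (26 genes, median -0.023, adjusted p = 0.0150, or 0.448 with an estimated correlation) and 7 common selection markers (median -0.052, adjusted p = 0.0475, or 0.703 with an estimated correlation) completed the lower lists. The 6 genes around ZTA1 passed upward (mean 0.51, median 0.0062, adjusted p = 0.0072, or 0.448 with an estimated correlation) through FMP23 and GIP1, which passed over all genes and adjusted over the list alone. Oxidative stress genes under Yap1 did not pass (34 genes, median -0.013, adjusted p = 0.263), and neither did genes of messenger RNA decay and AU-rich element binding (30 genes, median 0.014, adjusted p = 0.107).

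In all, 13 of 32 lists passed in untreated cells with the preset correlation, 3 upward and 10 downward, and none passed with the estimated correlation. Because few degrees of freedom also limit the latter test, here and in the other comparisons, its failures do not show that correlation between genes made the calls. Several calls ended when a single pair was left out. Without untreated replicate 1 this concerned the genes around ZTA1 (adjusted p = 0.0517), Msn2 and Msn4 stress genes (0.697), sulfur genes (0.0624), quinone reductases (0.127) and cytosolic ribosomal proteins (0.638). Without untreated replicate 2 it also concerned ribosome biogenesis (0.126), cytosolic ribosomal proteins (0.468) and the selection markers (0.832), and without untreated replicate 3 quinone reductases (0.110) and sulfur genes (0.110, median 0.0029). The selection markers also failed without any 1 of the H2O2 pairs, with adjusted p between 0.0695 and 0.0776. Other calls held with a median moved by more than 1.5 times, none with an adjusted p below 0.616 with an estimated correlation. Without untreated replicate 1 the medians were 0.012 for ribosome biogenesis and -0.098 for the selection markers, and without untreated replicate 2 the sulfur genes stood at -0.048. Without untreated replicate 3 the medians were 0.055 for ribosome biogenesis, 0.033 for cytosolic ribosomal proteins, 0.019 for the genes around ZTA1, -0.056 for Msn2 and Msn4 stress genes, -0.089 for iron genes and -0.082 for the selection markers.

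Under H2O2, the second comparison asked the same of cells exposed to peroxide. The genes directly beside ZTA1 passed again, as did several of the same small set. FMP23 was 3.81-fold higher (1.93 ± 0.17, SD, n = 3 pairs, limma adjusted p = 0.0152), NOB1 rose by 0.72 ± 0.022 (adjusted p = 6.9e-05), GIP1 by 0.62 ± 0.078 (adjusted p = 0.00072) and IMD2 by 0.42 ± 0.0027 (adjusted p = 0.0073). YCL021W-A fell by 3.66 on the log2 scale (SD 0.48), COS12 fell by 1.21 (SD 0.14) and YIR042C fell by 0.61 (SD 0.10).

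In peroxide-treated cells 4 further genes fell, all by less than 1.5-fold. SRX1 (YKL086W), the sulfiredoxin that restores oxidised peroxiredoxins, had a log2 ratio of -0.34 ± 0.095 (SD, n = 3 pairs, limma adjusted p = 0.0152). COS1 (YNL336W), of the same family as COS12, fell by 0.40 (adjusted p = 0.0249), YGP1 (YNL160W), a secreted cell wall glycoprotein, fell by 0.32 (adjusted p = 0.0339), and YPC1 (YBR183W), a ceramidase, fell by 0.23 (adjusted p = 0.0339). The size for YPC1 depended on the dye, at -0.36 with ∆zta1 in Cy5 and -0.097 with ∆zta1 in Cy3. In all, 4 genes rose and 8 fell, each in 3 of 3 pairs. YGL262W (-0.28, adjusted p = 0.0504) and YGL258W-A (-0.18, adjusted p = 0.0810) did not pass here. Leaving out single pairs kept 6 of the 12 calls throughout. FMP23, IMD2 and SRX1 failed whenever an H2O2 pair was left out (largest adjusted p 0.216, 0.129 and 0.14). These p-values rest on a spread shared with the untreated pairs and not on the SD of the H2O2 pairs alone. FMP23 stood at 2.11, 1.79 and 1.89 in the H2O2 pairs and at 2.89, 1.42 and 2.80 in the untreated pairs. For FMP23 and IMD2 the failures therefore do not mean that the H2O2 pairs disagreed. COS1, YGP1 and YPC1 failed in 4 or 5 of the 6 such fits, with adjusted p up to 0.244, 0.263 and 0.376. The number of genes passing was 7 without H2O2 replicate 1 and 6 without H2O2 replicate 3.

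The 8 genes that passed in both treatments were ZTA1, FMP23, GIP1, NOB1, IMD2, YCL021W-A, COS12 and YIR042C, all with the same direction in both. Independent lists of 11 and 12 genes would share 0.0236 genes on average. These lists could not be independent, because the same fit gave each gene a spread shared by both treatments. The deleted ZTA1 was also bound to be in both. No conclusion about the overlap is therefore drawn from that value.

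Among the lists, stress genes under Msn2 and Msn4 had a median of -0.078 under H2O2 (camera adjusted p = 3.3e-06, and adjusted p = 0.775 with an estimated correlation), with 4 of 38 above 0 and none passing over all genes or adjusted over the list alone. HXK1, hexokinase 1, had a ratio of -0.48, and GPH1, glycogen phosphorylase, had -0.29. Their list median was 0.027, -0.083 and -0.24 in the 3 H2O2 pairs, and the call ended without H2O2 replicate 3 (median -0.021, adjusted p = 0.421). Without H2O2 replicate 1 the median was -0.15 (adjusted p = 1.1e-14, or 0.506 with an estimated correlation). Respiration genes were lower in all 3 H2O2 pairs (55 genes, median -0.048, adjusted p = 3.2e-07, and adjusted p = 0.743 with an estimated correlation), with CYC7 at -0.20 and RIP1 at -0.14. Their median was -0.075 without H2O2 replicate 1 and -0.031 without H2O2 replicate 2, where the adjusted p with an estimated correlation was 0.506 and 0.773. Quinone or related reductases had a median of -0.054 (adjusted p = 0.0050, and adjusted p = 0.667 with an estimated correlation), with BDH2 at -0.17, and did not pass without H2O2 replicate 3 (adjusted p = 0.131). Phosphate-regulated genes had a median of -0.095 (adjusted p = 0.0080, and adjusted p = 0.743 with an estimated correlation), with PHO5 at -0.25, and did not pass without H2O2 replicate 1 (median -0.024, adjusted p = 0.454).

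Ribosome biogenesis genes were higher (median 0.028, adjusted p = 1.4e-05, and adjusted p = 0.930 with an estimated correlation), a direction that turned without H2O2 replicate 3 (median -0.0078, adjusted p = 0.942). Without H2O2 replicate 1 the median was 0.068 (adjusted p = 1.3e-19, or 0.593 with an estimated correlation). The PAU, DAN and TIR cell wall genes had a median of 0.023 (30 genes, adjusted p = 0.0474, and adjusted p = 0.930 with an estimated correlation). That call ended without any 1 of the untreated pairs (largest adjusted p = 0.0675) and without H2O2 replicate 1 (median -0.0034, adjusted p = 0.788). It held at 0.036 without H2O2 replicate 2 and at 0.038 without H2O2 replicate 3, with adjusted p of 0.810 and 0.998 with an estimated correlation. No member of these 6 lists passed over all genes or adjusted over the list alone. Oxidative stress genes under Yap1 did not pass as a list (median -0.032, adjusted p = 0.0872), although SRX1 passed over all genes and adjusted over the list alone. Without H2O2 replicate 1 the list passed as lower (median -0.074, adjusted p = 8.2e-07, or 0.506 with an estimated correlation). The arginine genes did not pass (median -0.058, adjusted p = 0.806), with ARG4 at -0.14 and ARG1 at -0.12.

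The third comparison asked whether the effect of losing ZTA1 differs between H2O2 and untreated cells. No gene passed in limma's test of that difference, nor in the other fits of all 6 pairs, and 71 of 5594 genes had an unadjusted p under 0.05, where chance alone gives 279.7. The count was also lower than that in untreated cells (204), and higher under H2O2 (464) and for the mean (529). So few small p-values mean that they were not spread as chance alone would spread them. The simulated runs had independent genes and no pair that stood apart, so the shares they found may not hold here. The smallest p among lower differences belonged to GIP1 (-0.36 ± 0.069, SE), YPC1 (-0.21 ± 0.045), SRX1 (-0.26 ± 0.059), MIX14 (-0.15) and GID10 (-0.14). The smallest among higher differences belonged to YGL262W (0.27 ± 0.060, SE), BOP2 (0.17 ± 0.049), YGL258W-A (0.15), BAS1 (0.20) and MIG2 (0.15). All of these had an adjusted p of 0.999 and did not pass, so genes that passed in a single treatment, such as SRX1 or BOP2, were not shown to respond differently. ZTA1 differed by 0.60 ± 0.35 (SE, adjusted p = 0.999).

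Without untreated replicate 2, whose ratios of ZTA1, FMP23 and GIP1 were the smallest in size among the untreated pairs, 3 genes passed. ZTA1 then differed by 1.09 (adjusted p = 0.0051), FMP23 by -0.91 (adjusted p = 0.0051) and GIP1 by -0.43 (adjusted p = 0.0423), each closer to 0 under H2O2. Ratios of this size also differed between the arrays of a pair. In H2O2 replicate 2, ZTA1 stood at -5.91 with ∆zta1 in Cy5 and at -3.21 with ∆zta1 in Cy3. The pair means of H2O2 replicates 1 and 3 were -4.96 and -4.58. Without intensities, a change in effect cannot be told apart from a smaller range of ratios on some arrays.

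Of the lists, 9 of 32 differed between treatments with the preset correlation, 6 upward and 3 downward, and none did so with the estimated correlation. Arginine (median difference 0.38), lysine (0.13) and other amino acid biosynthesis genes (0.13) were higher relative to wild type under H2O2 than in untreated cells, with adjusted p = 0.794 with an estimated correlation for each. Nitrogen catabolite (0.064), iron (0.040) and PAU, DAN and TIR genes (0.028) were also higher, and respiration (-0.040), cytosolic (-0.022) and mitochondrial ribosomal protein genes (-0.022) were lower. With an estimated correlation the adjusted p was 0.794 for nitrogen catabolite and respiration genes, 0.866 for iron genes and 0.872 for the other 3. No member of the 9 lists passed over all genes or adjusted over the list alone.

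None of these 9 calls held without untreated replicate 2, and 4 other lists passed in that fit. These were the genes around ZTA1 (median -0.028, adjusted p = 1.2e-05, or 0.440 with an estimated correlation), a-cell genes (-0.068, 0.0076, or 0.677), pheromone response genes (0.032, 0.0066, or 0.962) and ribosome biogenesis genes (0.027, 0.0026, or 0.962). With all 6 pairs the pheromone response genes stood at -0.033. Among the 9, the difference of the arginine genes was then 0.013 (adjusted p = 0.702), the lysine difference 0.011 (0.50) and that of the other amino acids 0.0056 (0.702). It was 0.018 for nitrogen catabolite genes (0.362), 0.011 for iron genes (0.580), 0.019 for PAU genes (0.0599), -0.012 for respiration (0.221), -0.011 for cytosolic ribosomal proteins (0.300) and 0.0054 for mitochondrial ones (0.221). Other pairs mattered for 4 of these lists. Cytosolic ribosomal proteins did not pass without untreated replicate 1 (0.346). Without H2O2 replicate 2 they turned upward (0.025, camera adjusted p = 0.0046 at the preset correlation), while mitochondrial ones stood at 0.0007 (0.960). With all 6 pairs neither list passed with an estimated correlation. Iron genes did not pass without H2O2 replicate 3 (0.231), and PAU genes did not pass without untreated replicate 3 (0.224) or H2O2 replicate 1 (0.765).

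Some of these differences held with a median moved by more than 1.5 times, none with an adjusted p below 0.704 with an estimated correlation. Without untreated replicate 1 the medians were 0.61 for arginine, 0.20 for lysine, 0.21 for other amino acids, -0.064 for respiration and -0.036 for mitochondrial ribosomal proteins. Without untreated replicate 3 they were 0.076 for iron genes, -0.043 for cytosolic and -0.039 for mitochondrial ribosomal proteins. Respiration stood at -0.072 without H2O2 replicate 1 and at -0.016 without H2O2 replicate 2. Cytosolic ribosomal proteins stood at -0.033 without H2O2 replicate 1 and at -0.058 without H2O2 replicate 3, where PAU genes stood at 0.042.

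The fourth comparison averaged both treatments over all 6 pairs. It gave 4 genes higher and 12 lower in ∆zta1, each with the same direction in 6 of 6 pairs, and 14 of the 16 had passed in at least 1 treatment. NOB1 (0.71 ± 0.063, SD, n = 6 pairs, limma adjusted p = 3.9e-06), GIP1 (0.80 ± 0.22, adjusted p = 8.1e-06), FMP23 (2.15 ± 0.58) and IMD2 (0.41 ± 0.085) rose. IMD2 stood at 0.20 with ∆zta1 in Cy5 and at 0.62 with ∆zta1 in Cy3. In the same order, YGL262W stood at -0.56 and -0.27, and YGL258W-A at -0.36 and -0.16. COS1 (-0.35, adjusted p = 0.0039), YGP1 (-0.25), SRX1 (-0.21) and GEX2 (YKR106W, a glutathione exchanger, -0.21, adjusted p = 0.0184) fell, besides YCL021W-A, COS12, YIR042C, YGL262W and YGL258W-A. The remaining falls, BOP2 (-0.16, adjusted p = 0.0375) and YPS6 (YIR039C, a cell surface protease, -0.17, adjusted p = 0.0184), lie outside the rule for naming genes and were named after their values were seen. Of the 16, 11 passed with any 1 pair left out. The others were YGP1, SRX1, GEX2, YPS6 and BOP2, with adjusted p up to 0.0991, 0.130, 0.132, 0.136 and 0.211.

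The 6 genes around ZTA1 differed sharply by position. FMP23 and GIP1, the adjacent genes, rose, while the next genes out, QDR3 (-0.12), TCM62 (-0.042), RPS11B (-0.052) and REB1 (0.023), did not pass. As a list over both treatments they did not pass in camera (mean 0.46 and the test upward, median -0.0095, adjusted p = 0.0523, or 0.600 with an estimated correlation) but passed upward in fry (adjusted p = 0.0209). They passed upward in camera without untreated replicate 2 (adjusted p = 0.0020), untreated replicate 3 (0.0399) or H2O2 replicate 1 (0.0462), with adjusted p of 0.601, 0.689 and 0.537 with an estimated correlation.

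**Figure D3:**
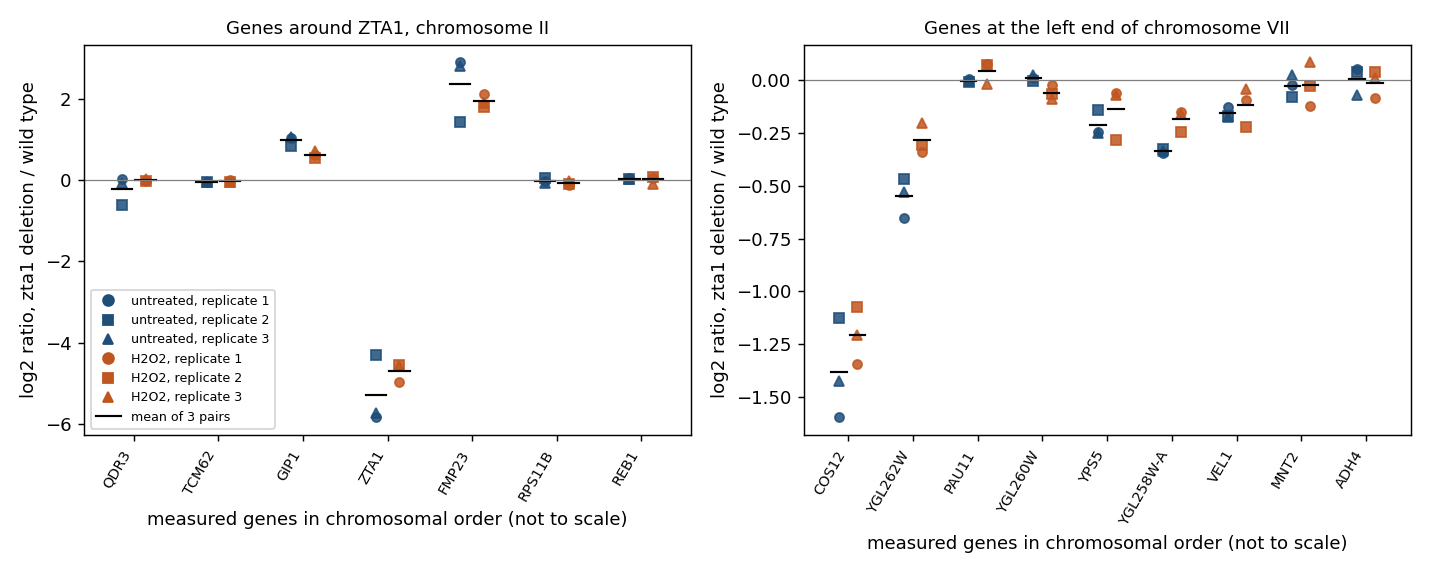
Log2 ratio of ∆zta1 over wild type (vertical axis) in each of the 6 pairs for genes in chromosomal order (horizontal axis, not to scale) around ZTA1 and at the left end of chromosome VII, with bars for the mean of 3 pairs per treatment. Among the genes around ZTA1, those directly beside it, FMP23 and GIP1, passed as higher, and COS12, at -1.30 over both treatments, was the lowest gene of the chromosome VII panel.

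Over both treatments 11 of 32 lists passed with the preset correlation, 1 upward and 10 downward, and none with the estimated correlation. Respiration (median -0.037, adjusted p = 1.0e-05, or 0.639 with an estimated correlation), phosphate-regulated genes (-0.064, adjusted p = 0.00011, or 0.598) and quinone or related reductases (-0.032, 0 of 18 above 0, adjusted p = 0.0012, or 0.537) passed with each pair left out in turn. Stress genes under Msn2 and Msn4 (-0.051, adjusted p = 1.4e-06, or 0.639) and ribosome biogenesis genes (0.027, adjusted p = 1.9e-07, or 0.639) did so too, although the sizes of some depended on single pairs. Without H2O2 replicate 3 the median was 0.0081 for ribosome biogenesis (adjusted p = 0.0443, or 0.857) and -0.023 for the stress genes (adjusted p = 0.0194, or 0.854). Without H2O2 replicate 1 it was 0.047 for ribosome biogenesis, -0.087 for the stress genes and -0.035 for phosphate-regulated genes, with 0.537, 0.502 and 0.537 with an estimated correlation. Ribosome biogenesis stood at 0.016 without untreated replicate 2 (or 0.780) and at 0.044 without untreated replicate 3 (or 0.689). No member of these 5 lists passed over all genes, and adjusted over the list alone 3 stress genes passed as lower. The calls for arginine (median -0.24), other amino acids (-0.070), lysine (-0.050), nitrogen catabolite (-0.032) and iron genes (-0.037) ended without untreated replicate 2. Their medians were then -0.056, -0.020, -0.017, -0.014 and -0.025, with adjusted p of 0.0937, 0.0550, 0.465, 0.445 and 0.0908. With all 6 pairs the adjusted p of these lists was 0.0030, 1.4e-06, 0.0134, 0.0076 and 0.00089, and adjusted p = 0.639 with an estimated correlation for each. The lysine genes and the sulfur genes (-0.043, adjusted p = 0.0056, or 0.598 with an estimated correlation) did not pass without H2O2 replicate 3, although their medians stayed at -0.056 and -0.034 (adjusted p = 0.0540 and 0.0967). Without untreated replicate 1 these medians were -0.079 and -0.028 and both passed (adjusted p = 0.699 for each with an estimated correlation), and iron genes stood at -0.065 without H2O2 replicate 3 (or 0.854). No member of these 6 lists passed over all genes or adjusted over the list alone.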

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

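The tests of the amino acid genes, of the neighbours of ZTA1 and of the placement of lower genes were chosen after the results were seen, apart from the median of the other genes near chromosome ends. The counts over other arrangements of the pairs were planned.

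The numbers of genes were set against other arrangements of the same pairs. For the mean of both treatments, the real signs gave 16 genes. Of the 32 sign patterns of the 6 pairs, 1, the real one, gave that many, and 0 genes was the highest of the others. The 16 include the deleted ZTA1, so the real signs were bound to be favoured. The count is therefore no separate evidence that the strains differ, and it does not exclude chance for any single gene. The 11 genes of untreated cells and the 12 of H2O2-treated cells each had 4 sign patterns of 3 pairs, of which 1 gave as many and the highest other gave 0. These patterns are too few for a share under 0.05. For the difference between treatments the real split gave 0 genes, as did the highest of the others, so 10 of 10 splits gave as many. Those splits too are too few for a share under 0.05.

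The lists whose strain effect differed between H2O2 and untreated cells in the camera test are given with the median difference of the log2 ratios. The values were 0.38 for arginine, 0.13 for lysine, 0.13 for other amino acid biosynthesis genes, 0.064 for nitrogen catabolite genes and 0.040 for iron genes. They were 0.028 for PAU, DAN and TIR genes, -0.040 for respiration, -0.022 for mitochondrial and -0.022 for cytosolic ribosomal protein genes. No difference passed with an estimated correlation, and without untreated replicate 2 none of them passed while 4 other lists did.

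Amino acid biosynthesis genes were lower in ∆zta1 in untreated replicate 2, with a median of -0.43 over 64 genes against 0.024 and -0.059 in the other untreated pairs. An error of a single array or dye is argued against by its 2 arrays, whose medians were -0.419 and -0.425. Peroxide-treated RNA in a channel would move the oxidative stress genes together, and their median in that pair was 0.012, with quartiles of -0.037 and 0.054. A fall caused by the deletion alone, alike in every culture, is not borne out either, because the lower median of the other untreated pairs was -0.0589. A difference between these 2 cultures in growth or nutrient state, or an effect of the deletion that depends on such a state, may remain and was not tested.

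The genes on both sides of ZTA1 were higher, FMP23 by 2.15 and GIP1 by 0.80 over both treatments. Extra copies of the region would raise the outer neighbours too, but their median was -0.0471, with a range from -0.12 to 0.023. An effect of the missing protein and an effect of the edited locus cannot be told apart with a single deletion allele. The highest ratio of any other gene was 0.706 (NOB1), below FMP23, so a local effect of the inserted or removed sequence is a candidate explanation that these arrays leave open.

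Of the 11 genes that fell over both treatments, ZTA1 left out, 7 were among the 20 measured genes nearest to a chromosome end, namely COS12, YGL262W, YGL258W-A, YIR042C, YPS6, COS1 and GEX2. Independent draws would give 1.26, but this count was made after the places of the genes were seen, and neighbours such as COS12 and YGL262W are not independent, so it does not exclude chance placement. Among the genes that rose, IMD2 (0.41) was number 3 from an end of chromosome VIII. It is counted neither among the 7 nor among the other genes named next. A general fall of the 20 genes nearest to each end is argued against by the other 632 of them. Their median was -0.0051 with quartiles of -0.037 and 0.022. A fall confined to the outermost few genes would be diluted in that median and was not tested. A difference in DNA between the strains at some ends, or signal shared within gene families, could give the same pattern, and neither was tested because the series holds no DNA data. No biological explanation was tested.

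Some probes with no gene in the annotation also differed over both treatments in a test of all 6256 probes. Probe A_06_P1129 had a log2 ratio of 0.32 ± 0.025 (SE, limma adjusted p = 0.00038) and was higher in 6 of 6 pairs. Probe A_06_P4020 had a log2 ratio of -0.36 ± 0.034 (SE, adjusted p = 0.0015) and was higher in 0 of 6 pairs.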

How the results depend on the processing

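The weighting of pairs by quality was chosen after the data were seen, and all other settings were planned. Results are given in the order untreated, H2O2, difference between treatments and mean of both, against 11, 12, 0 and 16 genes and 13, 6, 9 and 11 lists. Gene counts moved most with the dye, except for the difference between treatments. There only leaving out untreated replicate 2 moved the count, from 0 to 3. List counts fell most with the test of lists. Arrays with ∆zta1 in Cy5 alone gave 906, 929, 0 and 2063 genes and 6, 6, 8 and 4 lists, and those with ∆zta1 in Cy3 alone gave 562, 420, 0 and 1477 genes and 5, 3, 8 and 3 lists. By construction a dye effect does not cancel there. The 12 arrays in a single fit gave 13, 15, 0 and 30 genes, weighted pairs 13, 14, 0 and 28, an adjusted p under 0.01 gave 10, 7, 0 and 11, and a minimum of 1.5-fold left 7, 7, 0 and 7. Centring and scaling the arrays left 11, 12, 0 and 16 genes. The camera test with an estimated correlation called 0, 0, 0 and 0 lists and fry 1, 0, 0 and 1. With single pairs left out, the ranges were 9 to 12, 6 to 13, 0 to 3 and 11 to 22 genes, and 12 to 12, 5 to 12, 4 to 13 and 11 to 16 lists. Lists that passed only with a pair left out numbered 6, 10, 12 and 12, none of them with an estimated correlation. ZTA1 then ranged from -5.79 to -5.03 in untreated cells, from -4.77 to -4.57 under H2O2, from 0.325 to 1.085 for the difference, where it passed only without untreated replicate 2, and from -5.24 to -4.86 for the mean. With robust eBayes ZTA1 under H2O2 (-4.70) had an adjusted p of 0.0577 and did not pass. Medians of lists that had not passed with all 6 pairs could turn. Pheromone response genes in untreated cells went from 0.035 to -0.038 without untreated replicate 2. For lists that had passed, the median turned in these cases. With ∆zta1 in Cy5 alone it was -0.11 for cytosolic ribosomal proteins and -0.0030 for the genes around ZTA1, both in untreated cells. With ∆zta1 in Cy3 alone it was -0.0126 for PAU genes under H2O2 and 0.0033 for nitrogen catabolite genes in the mean. With single pairs left out, sulfur genes in untreated cells ranged from -0.0481 to 0.0029 (without untreated replicate 3). Under H2O2, ribosome biogenesis ranged from -0.0078 (without H2O2 replicate 3) to 0.0683 and PAU genes from -0.0034 (without H2O2 replicate 1) to 0.0376. For the difference, cytosolic ribosomal proteins ranged from -0.0583 to 0.0249 (without H2O2 replicate 2). Mitochondrial ones ranged from -0.0393 to 0.0054 (without untreated replicate 2) and stood at 0.0007 without H2O2 replicate 2. The cause was not tested beyond the dye. Among named genes, 1365 values kept their direction or had no call to lose, 57 no longer passed, 9 newly passed and 0 turned. Among values of lists that passed, 335 kept direction and call, 161 no longer passed and 10 turned. The replicate number as a block gave 10, 10, 0 and 13 genes and 14, 8, 11 and 13 lists. No sign that equal numbers pair the samples was seen: correlations of same-numbered deviations were -0.014, 0.031 and -0.27 across genes, and not every sample correlated best with its own number. Each value is already a ratio within a pair, in which shared conditions may cancel, so these correlations cannot settle whether equal numbers belong together. Intensities were not used here, so what the signal over background limits is unknown. Another background correction, a filter on dim probes and a slide block were not run, and a filter on genes with all 12 values removes nothing.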

Other observations

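The test that counts amino acid genes among the most variable genes was chosen after the values were seen, as were the genes named here.

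Several hexose transporter genes and related genes were among the 50 genes with the largest SD over the 6 pairs. They passed in neither treatment and were not tested as a group. HXT7, a high-affinity hexose transporter, had a log2 ratio of 1.04 in untreated replicate 2 and lay between -0.66 and -0.14 in the other 5 pairs. HXT4 (1.24), HXT6 (0.90), HXK1 (0.82) and MTH1 (0.99), a regulator of hexose transporter genes, were likewise above 0 in untreated replicate 2 and below 0 in the others. HXT2 was at 0.66 in untreated replicate 2 and at 0.075 in H2O2 replicate 3, and below 0 in the other 4 pairs. HXT6 and HXT7 are close copies, and whether their probes share signal was not tested. SNZ1 (-1.94) and SNO1 (-1.74), of vitamin B6 synthesis, and GGC1 (-1.19), a mitochondrial GTP and GDP carrier, were low in the same pair. GRS2, a second glycyl-tRNA synthetase gene, was instead low in H2O2 replicates 1 and 3 (-0.80 and -0.97).

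Among the 50 genes with the largest SD over the 6 pairs, 12 were amino acid biosynthesis genes, where independent draws would give 0.573. This count restates the low ratios of these genes in untreated replicate 2, which were seen first, and is no separate evidence that they vary together. Without that pair 2 of the 50 were such genes.

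The COS family was not tested as a group. Of the 11 measured genes with a COS name other than COS12, 10 had ratios below 0 over both treatments, with a median of -0.12. They ranged from -0.35 (COS1) to 0.085 (COS111), and COS1 alone of these passed. COS111 was included by its name only. It is number 91 from its chromosome end among measured genes, away from the family near telomeres. At the left end of chromosome VII, YPS5 (-0.17) and VEL1 (-0.14) lay below 0 without passing, while PAU11 (0.021) and YGL260W (-0.024), between COS12 and YGL258W-A, were near 0. For YCL021W-A, the gene lowest after ZTA1, the nearest measured genes were KCC4 (0.011) and LEU2 (-0.068), which did not pass. Genes that were not measured may lie between them, so these values do not bound the fall. Whether the DNA of YCL021W-A differs between the strains was not tested, so its low ratio is not shown to follow from the loss of ZTA1.

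Large ratios were smaller on some arrays. ZTA1 stood at -4.68 and -3.95 on the 2 arrays of untreated replicate 2, and FMP23 at 1.60 and 1.23. In H2O2 replicate 2, ZTA1 stood at -5.91 with ∆zta1 in Cy5 and at -3.21 with ∆zta1 in Cy3, and FMP23 at 2.45 and 1.12.

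Without untreated replicate 2, 6 further genes passed over both treatments. HSP12 (-0.29), SEO1 (-0.20), GEX1 (-0.16), COS7 (-0.14) and YPC1 (-0.14) were lower and YHL050C (0.18) was higher.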
